A study of Mus musculus with 38 samples.

How the data were processed

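Total RNA from mouse tissue was measured on 38 Illumina bead arrays. Per the labels, the samples were control tissue, or tissue of the tumor microenvironment taken 4 or 14 days after inoculation of C57BL/6 mice with the B16 melanoma lines B16-WT, B16-shTGFb or B16-shVEGF. The names shTGFb and shVEGF stand by convention for short hairpin RNAs against the growth factors TGF-beta and VEGF. The labels state that the tissue was lysed, that RNA was taken up in Trizol and cleaned on RNeasy columns with DNase I, and that biotin-labelled cRNA was made with the Ambion MessageAmp kit.

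The deposited non-normalized table gives for each of 45272 probes the signal intensity on each array, on the linear scale and without normalization. Beside each intensity, the deposited table holds a detection p-value, the p of that probe's signal against the negative controls of the same array. The deposited normalized table holds log2 intensity of 16247 probes. It was tested on the files to be the log2 of the quantile-normalized signals of these probes without background correction, with a largest difference of 5e-14. The submitters' processing notes name BeadStudio and limma, with versions not given in the sources used here. Every column of values belonged to a sample, and 0 columns were left without one. Scale, centring and direction of the values were settled from the files.

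Between 16519 and 22897 probes per array had a detection p under 0.05. The median raw signal per array lay between 105 and 155, and the median of the deposited log2 values between 8.50 and 8.57. The number of arrays limits the precision.

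The non-normalized signals were background-corrected with the normal-exponential model of limma, using the detection p-values in place of control probes, with an offset of 16, and were then quantile-normalized and taken as log2. Probes were named from the deposited annotation. Of the probes in the normalized table, 14836 had 1 gene symbol, 5 had several and 1406 had none, and 14830 of the named probes were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6. The filter required a detection p under 0.05 on at least 4 arrays and removed 0 named probes. Only probes of the deposited normalized table could be named, so the filter acted on a set already reduced. Each gene was represented by its probe with the highest mean, which gave 9890 genes, 3486 of them with more than 1 probe. A further 11751 detected probes without a gene name were tested in the same way and gave 0 calls over the 13 comparisons. These probes were outside the normalized table or had no symbol in it.

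The fit was a limma linear model with a mean for each of 7 labelled groups over all 38 arrays, with moderated variances and 13 comparisons between group means. The comparisons were each tumor group against control, the wild-type line at day 14 against day 4, each shTGFb or shVEGF group against the wild-type line on the same day, and the difference of these last differences between the days. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and a gene was called at an adjusted p under 0.05. Samples took their group from the labels alone. Array numbers are those of the sample titles. The descriptions give the same numbers for control and wild-type samples, and number 5 for every shTGFb and shVEGF sample.

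Written before the data were examined were the groups, the comparisons, the test, 29 gene lists and the rule for the genes to name. The rule named Tgfb1 and Vegfa, the 10 largest rises and 10 largest falls among called genes (5 and 5 for the shTGFb and shVEGF comparisons with control and for the differences between days), and from each list the 3 called members with the largest change or, where none was called, the member with the highest mean. As 0 genes were called, the rule named Tgfb1, Vegfa and 1 leading member of each list. All other genes in the text were chosen after their values were seen.

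The lists covered melanocyte and melanoma markers, cell cycle, T cells, regulatory T cells and checkpoints, cytotoxic lymphocytes, B cells, macrophages, alternatively activated macrophages, neutrophils, dendritic cells with MHC class II, mast cells, interferon response, inflammatory cytokines, TGF-beta genes, VEGF genes, blood endothelium, lymphatic endothelium, hypoxia and glycolysis, fibroblast and collagen genes, extracellular proteases, skeletal muscle, adipocytes, keratinocytes, hair follicle, mammary epithelium, erythroid cells, Schwann cells, immediate early genes and oxidative phosphorylation. Lists with at least 2 measured members, 28 in all, were tested with camera of limma, two-sided, with the correlation between genes estimated from the residuals. Lists were measured in part, such as 5 of 17 cytotoxic, 3 of 16 B cell and 6 of 22 hair follicle genes. Counts of list members in the text are of those measured. The erythroid list had 1 measured member and was tested as a gene only. Limma p-values were also adjusted over the measured members of each list alone, without correction for the number of lists. For the erythroid list this leaves the p-value unadjusted.

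The procedure was tested on simulated data with 200 changed genes among 9890 in 11 comparisons. With independent noise it recovered 23.9 to 43.3% of genes moved by log2 1, 73.1 to 89.6% of those moved by log2 2 and 87.9 to 95.5% of those moved by log2 3, with at most 13 unchanged genes called. With noise from shuffled arrays these shares were 25.4 to 43.3%, 62.7 to 89.6% and 81.8 to 93.9%, with at most 15 unchanged genes called. These values rest on 1 shuffle of the arrays per comparison. Among the splits of the arrays described below, some called up to 4626 genes, so the count of 15 is not a bound. A moved list of 20 genes had an unadjusted camera p under 0.05 in 11 of 11 comparisons with either noise. A list left in place had such a p in 1 comparison with independent noise and in 0 with shuffled arrays. The 20 genes were drawn at random, so this does not show how often camera calls a list whose genes vary together.

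Similarity of arrays was tested by Spearman correlation over all genes with 100000 permutations of the labels. Alternatives tried were no background correction, median scaling, the deposited normalized table, no detection filter, the mean of a gene's probes, array weights, a block for the replicate number, a fit of only the groups compared, a preset correlation of 0.01 between the genes of a list, and leaving out each array in turn. Added after the data were seen were the removal of 3 arrays with collagen genes near background, the removal of 2 arrays far from the others, and a fit with 5 tissue lists as covariates. A block for the slide was not run, since the files give no slide. Calculations used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9.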

Results

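Expression was measured in whole tissue of C57BL/6 mice, either control tissue or the tissue of growing B16 tumors, which come from a mouse melanoma line. There were 7 arrays labelled control, 4 labelled wild-type day 4, 5 labelled wild-type day 14, 6 labelled shTGFb day 4, 5 labelled shTGFb day 14, 5 labelled shVEGF day 4 and 6 labelled shVEGF day 14. Per array, 16519 to 22897 probes were detected at p under 0.05. Nothing in the labels says whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples. Values are log2 intensities after background correction and quantile normalization, and differences are limma's fitted log2 differences with their standard error (SE). Genes other than Tgfb1, Vegfa and the leading member of each gene list were chosen after their values were seen. For each comparison the count at an unadjusted limma p under 0.05 is given, where 494.5 genes would pass on average if none differed. Other splits of the arrays compared had median counts from 62 to 779 over the comparisons, so 494.5 is only a rough guide. No gene was called in any of the 13 comparisons at an adjusted limma p under 0.05. The differences below are therefore measured values and not called changes. Leaving out 1 array moved 332 of the 364 list medians of these comparisons by over 1.5 times and turned the sign of 131.

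The genes targeted in the shTGFb and shVEGF lines were not detectably lower in tissue with those labels. Tgfb1, which encodes a cytokine that restrains immune cells and drives matrix deposition, had a mean of 9.09 ± 0.65 (SD, n = 6) on the arrays labelled shTGFb day 4 and 8.77 ± 0.15 (SD, n = 4) on those labelled wild-type day 4. The fitted difference was 0.32, with a 95% interval from -0.62 to 1.27 and a limma adjusted p of 0.732. At day 14 the Tgfb1 means were 9.35 ± 0.56 (SD, n = 5) with shTGFb and 8.84 ± 0.78 (SD, n = 5) with wild-type labels, a difference of 0.51 with an interval from -0.42 to 1.44 (limma adjusted p = 0.554). Vegfa, which encodes the main growth factor of blood vessels, had a mean of 10.01 ± 0.43 (SD, n = 5) on the arrays labelled shVEGF day 4 and 10.05 ± 0.25 (SD, n = 4) on those labelled wild-type day 4. That difference was -0.04, with an interval from -0.81 to 0.72 (limma adjusted p = 1.00). On the day 14 arrays the Vegfa means were 9.91 ± 0.53 (SD, n = 6) with shVEGF and 10.19 ± 0.82 (SD, n = 5) with wild-type labels, a difference of -0.29 with an interval from -0.98 to 0.40 (limma adjusted p = 0.57). A dimmer probe of Vegfa gave -0.04 at day 4 and -0.20 at day 14. The arrays labelled control had means of 8.83 ± 0.34 for Tgfb1 and 9.99 ± 0.59 for Vegfa (SD, n = 7). Both genes were detected on all arrays. The tissue holds host cells beside tumor cells, and the arrays do not separate them.

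**Figure D1:**
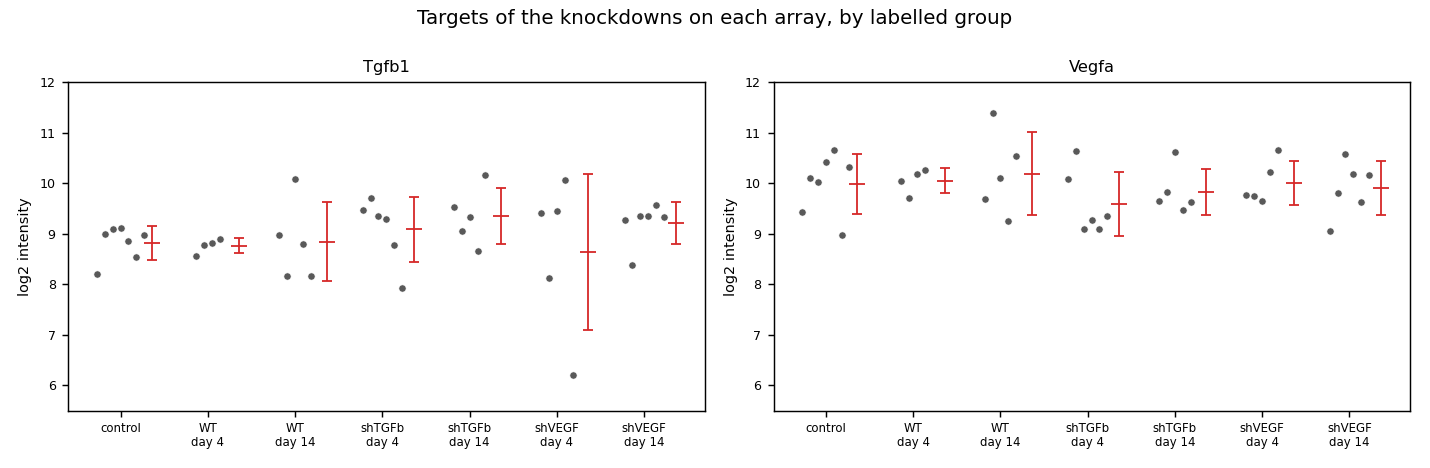
Log2 intensity of Tgfb1 (left) and Vegfa (right) on each array (points) by labelled group, with the group mean and 1 SD in red. The lowest Tgfb1 value, 6.20, is on an array labelled shVEGF day 4, and the 6 arrays labelled shTGFb day 4 span 7.92 to 9.71.

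Tissue composition differed widely between single arrays with the same label. Pigment cell genes were high on most arrays of every group, those labelled control included. Mlana, a melanosome protein gene, was detected on 6 of 7 arrays labelled control with a mean of 11.81 ± 3.30 (SD, n = 7), beside 12.97 ± 1.71 (SD, n = 4) on those labelled wild-type day 4 and 13.18 ± 1.52 (SD, n = 5) on those labelled wild-type day 14. Dct, an enzyme of melanin synthesis, had means between 12.69 ± 2.55 (SD, n = 6, shVEGF day 14) and 13.98 ± 0.54 (SD, n = 4, wild-type day 4). Krt71, a keratin of the hair root sheath, was detected on 22 of 38 arrays and reached 14.35 on control array 6 and 14.64 on wild-type day 14 array 4. Of the variance of the melanocyte list mean over the 38 arrays, 8.48% lay between the labelled groups, beside 32.0% for the collagen list and 14.1% for the hair follicle list. Principal component 1 held 52.4% of the variance over all genes, and 27.3% of its scores' variance lay between groups. The shares that shuffled labels give were not computed, so these shares are not set against chance. The mean Spearman correlation was 0.874 between arrays with the same label and 0.857 between arrays with different labels (one-sided permutation p = 0.0465). Within single labels it was below 0.857 for wild-type day 4 (0.782), wild-type day 14 (0.759) and shVEGF day 4 (0.818). Only control, at 0.932, had a one-sided permutation p under 0.05 (0.0425, adjusted 0.298). Only 3 of 38 arrays had their most similar array in their own labelled group, where chance gave 4.70 (one-sided permutation p = 0.796).

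**Figure D2:**
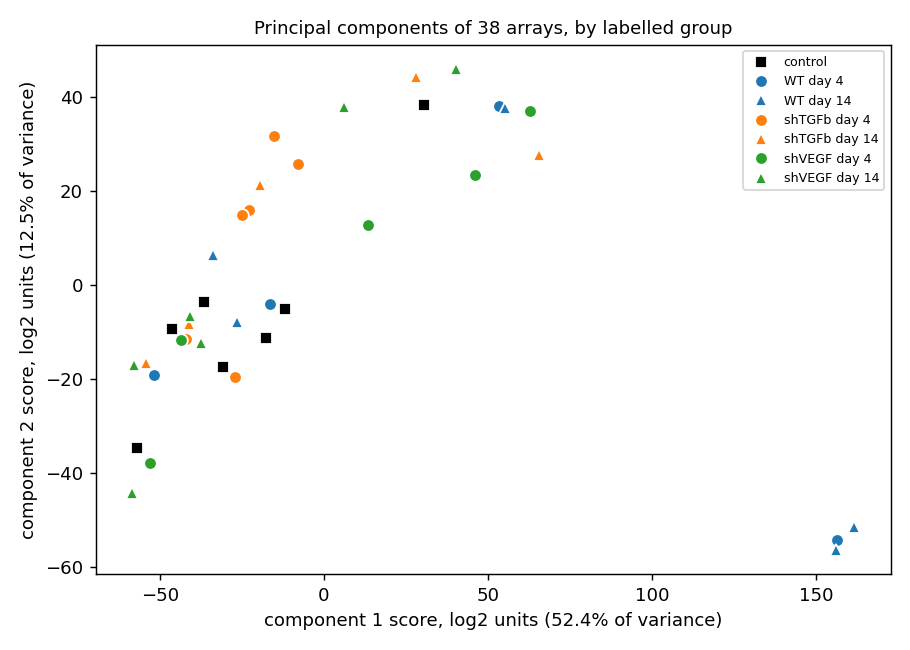
Scores of the 38 arrays on principal components 1 (52.4% of variance) and 2 (12.5%) in log2 units, colored by line and shaped by day. Wild-type day 4 array 4 and wild-type day 14 arrays 2 and 5 lie between 156 and 162 on component 1, and the next highest array is at 65.7.

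On 3 arrays the genes of host tissue were near background, and all 3 carried wild-type labels. They were wild-type day 4 array 4 and wild-type day 14 arrays 2 and 5. Dcn, which encodes the collagen-binding proteoglycan decorin, had values of 4.38, 4.67 and 4.86 on them and was not detected, while Dct had 14.06, 14.37 and 13.92. Their collagen list means were 5.39 to 5.68, and those of the other 35 arrays 9.32 to 11.76. Their cell cycle list means of 10.64 to 10.89 after normalization were above the highest other array at 10.41. Before normalization they were 10.80, 10.25 and 10.99 in the order named, beside 10.78 on the highest other array. Wild-type day 14 array 2 was thus below it. These 3 arrays enter every comparison with a wild-type group below, so the comparisons are given also without them, a choice made after the data were seen.

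**Figure D3:**
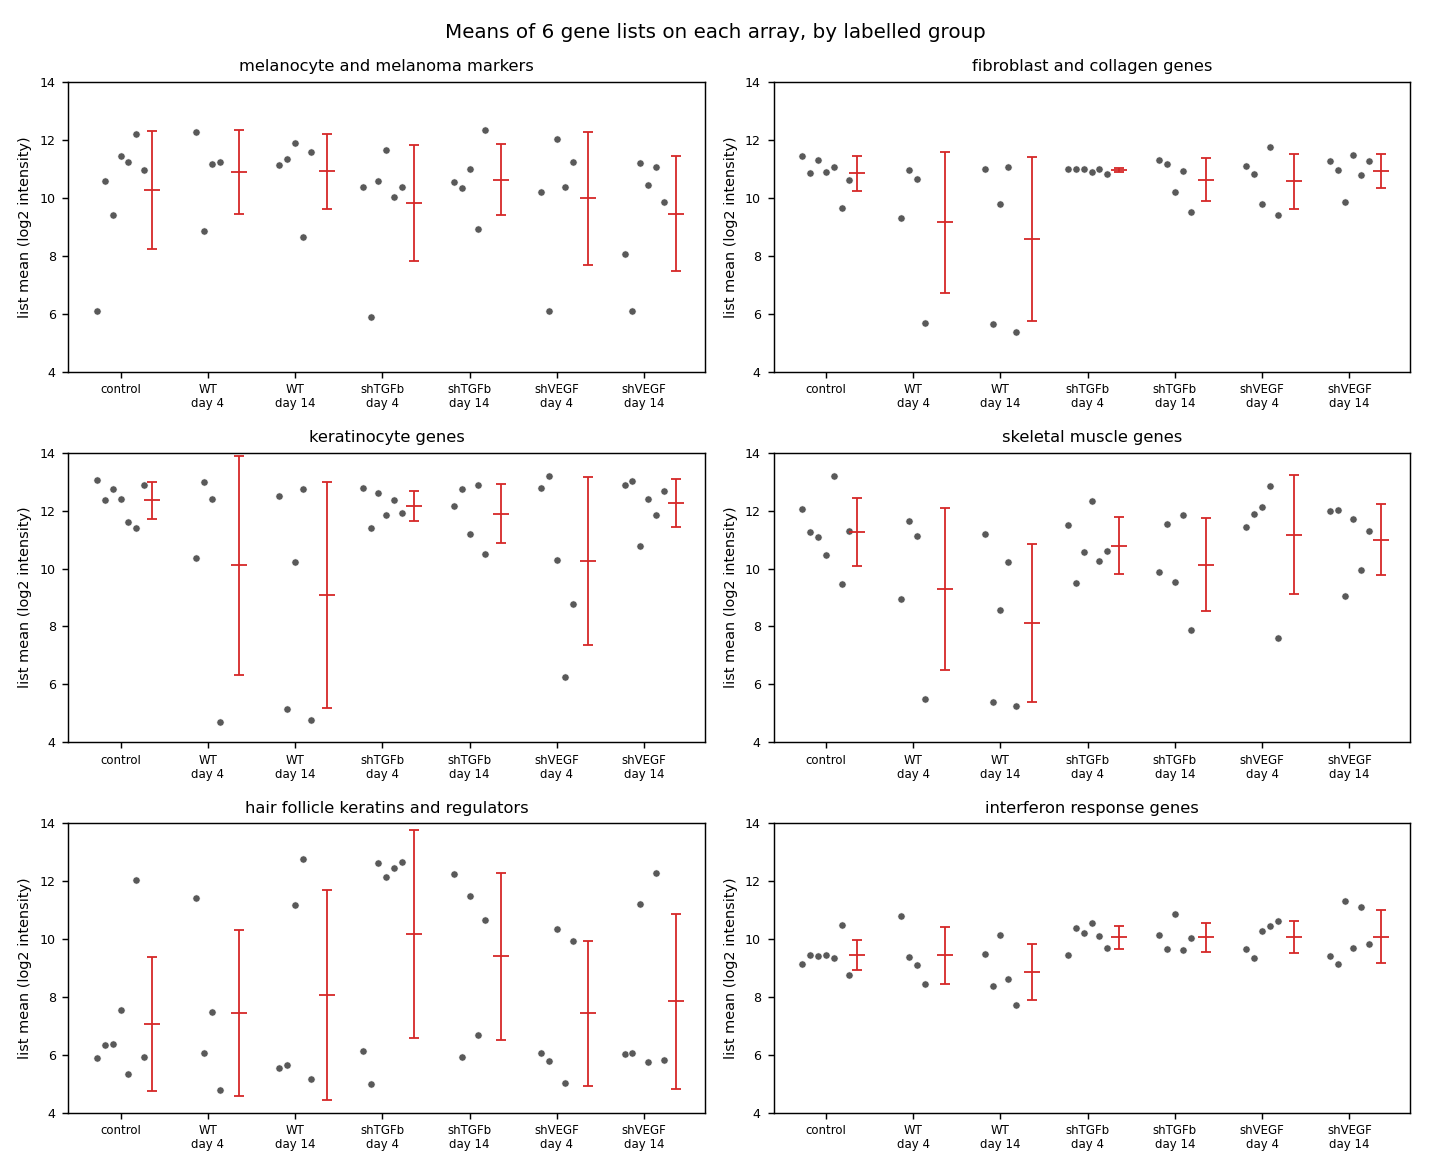
Mean log2 intensity of 6 gene lists on each array (points) by labelled group, with the group mean and 1 SD in red. The 3 lowest collagen list means, 5.39 to 5.68, carry wild-type labels, and the melanocyte list on the arrays labelled control spans 6.09 to 12.22.

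The arrays labelled wild-type day 4 were compared with those labelled control to show what early tumor tissue adds to or lacks beside control tissue. Connective, muscle, fat and skin genes had lower means on the tumor arrays. Dcn had a mean of 11.28 ± 4.67 (SD, n = 4) against 14.10 ± 0.45 (SD, n = 7) in control, a difference of -2.82 (SE 1.41, limma adjusted p = 0.725). Myl1, a light chain of muscle myosin, had a difference of -2.60 (SE 1.41) and Krt14, a keratin of the basal epidermis, one of -2.54 (SE 1.45). On wild-type day 4 array 4 Krt14 was near background at 4.47, beside 13.80 to 14.54 on the other arrays with that label. The size of its difference rests on that array. Cell cycle genes had small positive differences, with 0.31 (SE 0.32) for Cenpa, a histone of the centromere. All 21 measured collagen list genes had negative differences (median -1.64), as did 26 of 26 muscle genes (median -2.01), 15 of 15 adipocyte genes (median -1.59), 18 of 18 keratinocyte genes (median -2.35) and 16 of 16 macrophage genes (median -1.39). For each of these lists the camera adjusted p was 0.411 with an estimated correlation. All 19 cell cycle genes had positive differences (median 0.54, camera adjusted p = 0.472). The oxidative phosphorylation list had a median of 0.07 and an upward test but a mean of -0.17 (camera adjusted p = 0.955). In total 0 genes were called by limma over all genes and 0 adjusted over the list alone, with 196 genes at an unadjusted p under 0.05 (82 higher, 114 lower) and a smallest adjusted p of 0.725. Without wild-type day 4 array 4, 1 of the 3 host-poor arrays, the Dcn difference was -0.52 and 4 genes had an unadjusted p under 0.05, in the limma fit that left out all 3. The medians were then -0.52 for the collagen list, -0.67 for muscle, -0.65 for adipocytes, -0.35 for keratinocytes, -0.12 for macrophages and 0.24 for the cell cycle.

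The arrays labelled wild-type day 14 also had lower means of host tissue genes than control. Skeletal muscle genes had a median difference of -3.29, with Myl1 at 10.20 ± 4.64 (SD, n = 5) against 14.28 ± 0.44 (SD, n = 7) in control, a difference of -4.07 (SE 1.32, limma adjusted p = 0.143). Keratinocyte genes had a median of -3.46, with -3.61 (SE 1.35) for Krt14, and collagen list genes one of -2.31, with -3.95 (SE 1.32) for Dcn and -2.31 (SE 0.72) for Pdgfra, a growth factor receptor of fibroblasts. Macrophage genes had a median of -1.80, with -3.43 (SE 1.15) for Lyz1, a lysozyme gene of this list. Cd74, the invariant chain of MHC class II, had a difference of -2.87 (SE 1.01), and Mcpt4, a mast cell protease, one of -2.42 (SE 0.93). Cell cycle genes were higher on the tumor arrays for 19 of 19 members (median 0.74), with 0.66 (SE 0.30) for Cenpa. By limma 0 of 9890 genes were called, with 2477 at an unadjusted p under 0.05 (822 higher, 1655 lower) and a smallest adjusted p of 0.143.

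When adjusted over the list alone, 124 genes in 17 lists passed in this comparison. They were 24 of 26 muscle, 18 of 21 collagen, 16 of 18 keratinocyte, 14 of 16 macrophage, 11 of 15 adipocyte, 11 of 21 blood endothelial, 7 of 16 dendritic cell, 4 of 6 mast cell and 3 of 4 lymphatic genes, and at most 3 genes in each of 8 other lists, all with negative differences. Vwf, a clotting factor of endothelium, had -2.18 (SE 0.63) and Lyve1, a receptor of lymphatic endothelium, -2.43 (SE 0.81). Among VEGF genes Vegfd, Flt1 and Nrp1 passed over the list alone, and this list had a median of 0.19 but a mean of -0.48 and a downward test (camera adjusted p = 0.514). In the TGF-beta list Tgfbi, a matrix protein induced by TGF-beta, passed over the list alone at -3.18 (SE 0.95). With an estimated correlation none of the 28 lists was called, and the smallest camera adjusted p was 0.379, shared by the muscle, keratinocyte, collagen, adipocyte, macrophage, dendritic cell, cytotoxic, blood endothelial, lymphatic and Schwann cell lists. The oxidative phosphorylation list had a median of 0.16 and a mean of -0.22, with an upward test (camera adjusted p = 0.858). Without the 3 host-poor arrays the differences were -0.36 for Dcn, -0.75 for Myl1 and -0.12 for Krt14, and 79 genes had an unadjusted limma p under 0.05. The medians were then -1.32 for muscle, -0.51 for keratinocytes, -0.21 for the collagen list, -0.23 for macrophages and 0.25 for the cell cycle. The number of calls depended on single arrays, with 1436 genes called by limma without wild-type day 14 array 1 and 1271 without wild-type day 14 array 4. Both of these fits kept the host-poor arrays of that group, and the fit without the 3 host-poor arrays called no gene.

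Of the other lists none was called between the arrays labelled wild-type day 14 and control. Interferon response genes had a median of -0.59 with 4 of 20 positive (camera adjusted p = 0.514 with an estimated correlation). It was -0.38 without wild-type day 14 array 5, -0.10 with array weights, and -0.18 with 8 of 20 positive without the 3 host-poor arrays. Alternatively activated macrophage genes had a median of -1.35 (0.483), with -3.01 (SE 1.33) for Retnla, a secreted marker of this state. Neutrophil genes had a median of -0.38 (0.762), with -2.40 (SE 0.87) for Il1r2, a decoy receptor of interleukin 1. T cell genes had a median of -0.46 (0.514), with -0.38 (SE 0.20) for Cd8b1, and regulatory T cell and checkpoint genes one of -0.51 (0.514), with 0.15 (SE 0.41) for Cd274, the ligand of the checkpoint receptor PD-1. Cd8b1 lay between 10.27 and 11.85 on all 38 arrays. Its lowest value was on wild-type day 14 array 2, where the T cell gene Cd3g was at 4.36, so Cd8b1 followed this list poorly. Lymphatic genes had a median of -2.16 (0.379), with -0.36 (SE 0.24) for Pdpn, a glycoprotein also found on fibroblasts and keratinocytes. Immediate early genes had a median of -0.58 (0.514), with -0.02 (SE 0.39) for Klf6, extracellular proteases one of -0.53 (0.514) and inflammatory genes one of -0.96 (0.483). B cell genes had a median of -0.18 (0.858), mammary epithelium genes one of -0.52 (0.880), Schwann cell genes one of -0.59 (0.379), and the erythroid gene Alas2 a difference of -1.11 (SE 0.56). Melanocyte genes were higher for 12 of 13 members (median 0.93, 0.816), as were hair follicle genes for 4 of 6 (median 1.25, 0.858) and hypoxia and glycolysis genes for 10 of 17 (median 0.07, 0.880). The sign turned without 1 array labelled wild-type day 14 for the neutrophil list (0.15 without array 2), the hair follicle list (-0.15 without array 4) and the hypoxia list (-0.07 without array 5), and without control array 1 the melanocyte median was 0.07.

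Day 14 and day 4 were compared within the wild-type labels to follow the growing tumor. Muscle, skin and immune genes had lower means at day 14, and cell cycle genes slightly higher ones. Myl1 had a difference of -1.47 (SE 1.51, limma adjusted p = 1.00) and Krt14 one of -1.07 (SE 1.55), with list medians of -1.20 over 26 muscle and -1.04 over 18 keratinocyte genes. Interferon response genes were lower for 19 of 20 members (median -0.59), with -1.25 (SE 0.51) for Irf7, a transcription factor of interferon induction, and -0.30 (SE 0.43) for Irf1. That median was -0.14 with 6 of 20 positive without wild-type day 4 array 1, -0.25 without wild-type day 14 array 5 and -1.02 without wild-type day 4 array 4. With array weights it was -0.02 with 8 of 20 positive. The macrophage list had a median of -0.53, the dendritic cell list one of -0.61 and the cytotoxic list one of -0.69. With an estimated correlation the camera adjusted p was 0.665 for the muscle, interferon, macrophage, dendritic cell and cytotoxic lists and 0.756 for the keratinocyte list. Limma called 0 genes over all genes and 0 adjusted over the list alone, with 63 at an unadjusted p under 0.05 (24 higher, 39 lower) and a smallest adjusted p of 0.836. Signs of median, mean and test differed for the melanocyte list (median -0.07, mean 0.03), the B cell list (0.06 and -0.03), the immediate early list (0.03 and -0.09) and the oxidative phosphorylation list (0.02 and -0.05), each tested upward, and for the protease list, tested upward with a median of -0.15. Host-poor arrays made up 1 of 4 at day 4 and 2 of 5 at day 14, and without them the difference of Myl1 was -0.39 and that of Dcn 0.16. The medians were then -0.56 for muscle, -0.07 for keratinocytes, -0.39 for interferon, 0.09 for macrophages, -0.19 for dendritic cells and -0.44 for the cytotoxic list. The sign turned without wild-type day 14 array 5 for the keratinocyte list (0.08) and the macrophage list (0.15), and without wild-type day 4 array 2 for the cell cycle list (-0.19, beside 0.25 with all arrays).

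The arrays labelled shTGFb day 4 were compared with those labelled wild-type day 4 for differences of early tumor tissue between the lines. No line with a control hairpin was among the labels, so the hairpin cannot be told apart from other differences between the lines. Host tissue genes had higher means with shTGFb labels, and glycolysis and cell cycle genes lower ones. Dcn had a mean of 14.08 ± 0.16 (SD, n = 6) against 11.28 ± 4.67 (SD, n = 4), a difference of 2.80 (SE 1.45, limma adjusted p = 0.505). Ldha, a subunit of the enzyme that turns pyruvate into lactate, had -0.37 (SE 0.19), and Mbp, a myelin protein also made by other cells, -1.71 (SE 0.70). Tgfbr2, a TGF-beta receptor, had 0.67 (SE 0.46), and the TGF-beta list a median of 0.32 with 15 of 19 positive differences (camera adjusted p = 0.341). The median differences were 1.94 for the collagen list (21 of 21 positive), 2.16 for keratinocytes (18 of 18), 1.37 for macrophages (16 of 16), 0.90 for T cells (10 of 11; 0.39 without shTGFb day 4 array 2 and 1 array labelled shVEGF day 4), -0.66 for the cell cycle (0 of 19 positive) and -0.72 for hypoxia and glycolysis (2 of 17). The camera adjusted p with an estimated correlation was 0.341 for each of these lists. Of all 38 arrays, the hypoxia list mean was highest on host-poor wild-type day 4 array 4 (11.16). It was lowest on shTGFb day 4 array 2 (9.54), and both arrays enter this difference.

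Limma called 0 genes over all genes in the shTGFb day 4 comparison with wild-type, with 811 at an unadjusted p under 0.05 (420 higher, 391 lower) and a smallest adjusted p of 0.505. Adjusted over the list alone, 4 genes passed. They were S100a8, a calcium-binding protein of neutrophils (3.14, SE 1.03), Kit, the stem cell factor receptor of mast cells and melanocytes (1.14, SE 0.39), and from the mammary epithelium list Elf5, an epithelial transcription factor (1.93, SE 0.46), and Cldn3, a tight junction protein (1.83, SE 0.59). The hair follicle list had a median of 3.06 and the mammary list one of 1.77 (camera adjusted p = 0.341 for both). Leaving out the 3 host-poor arrays, 1 of them among the 4 labelled wild-type day 4, gave 0.50 for Dcn and 163 genes at an unadjusted limma p under 0.05. The medians were then 0.69 for the collagen list, 0.22 for keratinocytes, 0.15 for macrophages, -0.43 for the cell cycle and 1.95 for hair follicle. With array weights, which gave wild-type day 4 array 4 a weight of 0.157 and array 3 a weight of 7.07, limma called 855 genes (406 higher, 449 lower), Vegfa among them at -0.77 (adjusted p = 0.0317).

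At day 14 the arrays labelled shTGFb had higher means of immune, interferon, vessel and matrix genes than those labelled wild-type. Macrophage genes were higher for 16 of 16 members (median 1.74), with Lyz1 at 14.08 ± 0.45 (SD, n = 5) against 10.83 ± 4.36 (SD, n = 5), a difference of 3.25 (SE 1.24, limma adjusted p = 0.328). Interferon response genes were higher for 19 of 20 members (median 1.19), with 1.93 (SE 0.48) for Irf7, 0.87 (SE 0.41) for Irf1 and 1.31 (SE 0.36) for Stat2, a transducer of interferon signals. Prf1, the pore-forming protein of killer cells, had 1.18 (SE 0.45) in a cytotoxic list with a median of 1.33 (5 of 5 positive). Cd74 had 3.02 (SE 1.09) in the dendritic cell and MHC class II list, with a median of 1.53. Ccl9, a chemokine of myeloid cells, had 3.34 (SE 1.23) in the inflammatory list, with a median of 1.29. With an estimated correlation the camera adjusted p was 0.263 for the macrophage, interferon, cytotoxic, dendritic cell, inflammatory and blood endothelial lists, the last with a median of 1.20.

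Over all genes limma called 0 in the shTGFb day 14 comparison with wild-type, with 1403 at an unadjusted p under 0.05 (757 higher, 646 lower) and a smallest adjusted p of 0.307. Adjusted over the list alone, 58 genes in 8 lists passed. They were 14 macrophage, 10 interferon, 9 collagen, 9 dendritic cell, 8 blood endothelial, 4 cytotoxic and 3 VEGF genes with positive differences, and the single erythroid gene Alas2, an enzyme of heme synthesis, at 1.39 (SE 0.60). As the only measured member of its list, Alas2 passed at what is an unadjusted limma p under 0.05. The VEGF genes were Flt1, a VEGF receptor (2.21, SE 0.83), Nrp1, a co-receptor (0.89, SE 0.31), and Vegfd, a ligand of lymphatic vessels (2.18, SE 0.80). Keratinocyte genes had a median of 2.80 and muscle genes one of 2.12, with none past the threshold over the list alone (camera adjusted p = 0.342 for both). Signs differed for the mammary list (median -0.08, mean 0.05, tested upward), the hypoxia list (-0.03 and 0.09, upward) and the oxidative phosphorylation list (-0.17 and 0.13, downward). Removing the 3 host-poor arrays, 2 of them among the 5 labelled wild-type day 14, gave -0.09 for Dcn, 0.14 for Lyz1 and 0.38 for Irf1, and 24 genes had an unadjusted limma p under 0.05. The medians were then 0.65 for interferon (20 of 20 positive), 0.20 for macrophages, 0.28 for the cytotoxic list, 0.19 for dendritic cells, 0.26 for the inflammatory list, 0.23 for blood endothelium, 0.07 for keratinocytes and 0.17 for muscle. Without wild-type day 14 array 1 limma called 1 gene, Xkr7, at -1.24 (adjusted p = 0.0478), beside -1.08 (SE 0.22) with all arrays.

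The change of the shTGFb minus wild-type difference from day 4 to day 14 was tested directly. Hypoxia and glycolysis genes had a positive difference for 16 of 17 members (median 0.65), with 0.34 (SE 0.27) for Ldha and 1.10 (SE 0.51) for Slc2a1, a glucose transporter. Mammary epithelium genes had a negative one for 8 of 8 members (median -1.63), with -1.77 (SE 1.56) for Krt8, a keratin of simple epithelia. Both lists had a camera adjusted p of 0.349 with an estimated correlation. Of all 38 arrays, the hypoxia list mean was highest on host-poor wild-type day 4 array 4 (11.16). It was lowest on shTGFb day 4 array 2 (9.54), and both arrays enter this comparison. Tgfb1 had 0.19 (SE 0.65). Limma called 0 genes over all genes, with 137 at an unadjusted p under 0.05 (54 higher, 83 lower) and a smallest adjusted p of 1.00, and 1 adjusted over the list alone, Elf5 at -2.28 (SE 0.64). The T cell list had a median of 0.18 and a mean of 0.04 but a downward test, the neutrophil list a median of 0.10, a mean of -0.32 and a downward test, and the mast cell list a median of 0.04, a mean of -0.07 and a downward test. Without wild-type day 4 array 4 alone the mammary median was -1.02, and without the 3 host-poor arrays it was -2.43 and 97 genes had an unadjusted limma p under 0.05.

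The arrays labelled shVEGF day 4 were compared with those labelled wild-type day 4 for differences between these lines, again without a line with a control hairpin. Muscle, macrophage and matrix genes had higher means with shVEGF labels. Myl1 had a mean of 13.74 ± 1.73 (SD, n = 5) against 11.67 ± 4.57 (SD, n = 4), a difference of 2.07 (SE 1.51, limma adjusted p = 1.00). Lyz1 had 1.95 (SE 1.32) and Ccl9 2.01 (SE 1.30). Median differences were 1.99 for muscle (26 of 26 positive), 1.58 for macrophages (16 of 16), 1.53 for the collagen list (20 of 21), 1.00 for blood endothelium (18 of 21), 0.97 for inflammatory cytokines (12 of 14) and 0.46 for extracellular proteases (15 of 18), whose leading member Ctsb, a lysosomal protease, had 0.25 (SE 0.23). The camera adjusted p with an estimated correlation was 0.311 for each of these lists, and 0.905 for the keratinocyte list (median 0.09). The VEGF list had a median of 0.07 (camera adjusted p = 0.403), with -0.24 (SE 0.65) for Vegfb, another VEGF ligand. Limma called 0 genes over all genes and 0 adjusted over the list alone, with 252 at an unadjusted p under 0.05 (169 higher, 83 lower) and a smallest adjusted p of 0.692. Without the 3 host-poor arrays the differences were -0.17 for Myl1 and -0.13 for Lyz1, the keratinocyte list had a median of -1.68 with 0 of 18 positive (camera adjusted p = 0.533), and 70 genes had an unadjusted limma p under 0.05. The other medians were then 0.41 for muscle, 0.30 for macrophages, 0.27 for the collagen list, 0.26 for blood endothelium and 0.41 for inflammatory cytokines, and that of the proteases was 0.20 without shVEGF day 4 array 4.

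At day 14 the arrays labelled shVEGF had higher means of nearly all host tissue and immune lists than those labelled wild-type, and lower means of cell cycle genes. Myl1 had a mean of 14.12 ± 0.57 (SD, n = 6) against 10.20 ± 4.64 (SD, n = 5), a difference of 3.92 (SE 1.36, limma adjusted p = 0.141). Dcn had 3.79 (SE 1.36), Krt14 3.70 (SE 1.40), Lyz1 3.42 (SE 1.19), Cd74 3.05 (SE 1.04) and Mcpt4 2.44 (SE 0.96). Irf7 had the smallest p of all genes, with a difference of 2.27 (SE 0.46, limma adjusted p = 0.0969). Cell cycle genes were lower for 19 of 19 members (median -1.08), with -0.86 (SE 0.31) for Cenpa. Vwf had 2.32 (SE 0.65) and Egfl7, a factor secreted by endothelium, -0.34 (SE 0.33). Of all arrays, Egfl7 was highest, at 12.36, on host-poor wild-type day 4 array 4, where the blood endothelial list mean was 6.09. By limma 0 genes were called over all genes, with 2543 at an unadjusted p under 0.05 (1637 higher, 906 lower).

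Adjusted over the list alone, 133 genes in 18 lists passed in the shVEGF day 14 comparison with wild-type. They were 21 of 26 muscle, 18 of 21 collagen, 15 of 16 macrophage, 14 of 21 blood endothelial, 13 of 18 keratinocyte, 11 of 20 interferon and 8 of 16 dendritic cell genes with positive differences, and at most 6 genes in each of 11 other lists. In the regulatory T cell list Foxp3, the transcription factor of these cells, passed at -0.60 (SE 0.21), and in the T cell list Cd3g, a chain of the T cell receptor complex, at 2.24 (SE 0.72). The median differences were 2.96 for muscle, 3.34 for keratinocytes, 2.38 for the collagen list, 2.11 for macrophages, 1.36 for interferon response and -1.90 for the melanocyte list. With an estimated correlation none of the 28 lists was called, with a camera adjusted p of 0.311 for each of these lists except the melanocyte list, which had 0.466, and of 0.311 for the cell cycle list. The hair follicle list had a median of -0.39 and an upward test, and the oxidative phosphorylation list a median of -0.17, a mean of 0.20 and a downward test. Without the 3 host-poor arrays the differences were 0.60 for Myl1, 0.21 for Dcn, 0.22 for Krt14 and 0.32 for Lyz1, with 124 genes at an unadjusted limma p under 0.05. The medians were then 0.99 for muscle, 0.42 for keratinocytes, 0.33 for the collagen list, 0.38 for macrophages, 0.73 for interferon, -1.06 for the melanocyte list and -0.49 for the cell cycle. The melanocyte median was -0.90 without shVEGF day 14 array 2 alone. Single arrays again decided the call, since limma called 1210 genes without wild-type day 14 array 1, 1627 without array 4, and without array 3 only Irf7, at 2.57 (adjusted p = 0.0479). Each of these fits kept the host-poor arrays of that group, and the fit without the 3 host-poor arrays called no gene.

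For the change of the shVEGF minus wild-type difference from day 4 to day 14, keratinocyte genes had a positive value for 18 of 18 members (median 3.09), with 2.54 (SE 2.09) for Krt14. Collagen list genes had one for 21 of 21 (median 1.06), and cell cycle genes a negative one for 19 of 19 (median -0.77), with -0.72 (SE 0.47) for Cenpa. The camera adjusted p with an estimated correlation was 0.793 for each of these lists. Limma called 0 genes over all genes, with 100 at an unadjusted p under 0.05 (48 higher, 52 lower) and a smallest adjusted p of 0.988, and 1 adjusted over the list alone, Klrk1, an activating receptor of killer cells, at 1.22 (SE 0.43). Signs differed for the neutrophil list (median -0.22, mean 0.03, tested downward), the VEGF list (-0.01 and 0.19, upward), the protease list (-0.08 and 0.01, downward) and the hair follicle list (-0.31 and -0.20, upward). The fit without the 3 host-poor arrays had 43 genes at an unadjusted limma p under 0.05, with medians of 2.13 for keratinocytes, 0.11 for the collagen list and -0.51 for the cell cycle. Leaving out 1 array gave 1.95 to 4.97 for keratinocytes, 0.21 to 1.87 for the collagen list and -1.12 to -0.32 for the cell cycle.

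Against control, the arrays labelled shTGFb day 4 had higher means of hair follicle, mammary epithelium and interferon genes, and 1 array among them had high lymphocyte genes. Their keratinocyte list mean was not higher, at 12.2 beside 12.4 in control. Hair follicle genes were higher for 6 of 6 members (median 3.65), with Krt71 at 11.17 ± 5.15 (SD, n = 6) against values from 4.39 to 14.35 (n = 7) in control, a difference of 4.48 (SE 2.45, limma adjusted p = 0.999). Dlx3, a transcription factor of hair and skin, had 1.84 (SE 1.06). T cell genes had a median of 0.84 (9 of 11 positive), B cell genes one of 0.92 (3 of 3), with 1.30 (SE 0.69) for Cd79b, a chain of the B cell receptor, and interferon genes one of 0.51 (20 of 20). Hypoxia and glycolysis genes had a median of -0.47 (3 of 17 positive). ShTGFb day 4 array 2 stood apart with Cd79b at 12.65, and without it and 1 array labelled shVEGF day 4 the difference of Cd79b was 0.20 and the medians were 0.11 for B cells, 0.35 for T cells, 0.49 for mammary epithelium, -0.29 for hypoxia and 4.92 for hair follicle. The camera adjusted p with an estimated correlation was 0.358 for the hair follicle list and the mammary list (median 1.00), 0.372 for T cell and interferon genes and 0.435 for B cell and hypoxia genes. Over all genes 0 were called by limma, with 297 at an unadjusted p under 0.05 (179 higher, 118 lower) and a smallest adjusted p of 0.675, and 1 adjusted over the list alone, Elf5 at 1.50 (SE 0.40). The alternatively activated macrophage list had a median of -0.04 with a mean of 0.03 and the mast cell list a median of -0.02 with a mean of 0.14, both with an upward test, and the macrophage list had a median of 0.03 with a mean just under 0. Without shTGFb day 4 array 1 limma called 5 genes, Lef1, a transcription factor of hair follicle growth (2.27), B3gnt5 (2.70) and 3 members of a family of near-identical protease inhibitors, Serpina1b (2.60), Serpina1d (2.54) and Serpina1e (3.26), with adjusted p from 0.0161 to 0.0415. With array weights limma called 778 genes (400 higher, 378 lower), Vegfa among them at -0.79 (adjusted p = 0.014).

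The arrays labelled shTGFb day 14 differed little from control in most lists. Interferon response genes had a median of 0.51 (18 of 20 positive), with 0.49 (SE 0.38) for Irf1 and 0.61 (SE 0.33) for Stat2. Hair follicle genes had a median of 2.76 (5 of 6 positive), and muscle genes one of -1.14 (0 of 26 positive), with Myl1 at 13.53 ± 1.25 (SD, n = 5) against 14.28 ± 0.44 (SD, n = 7), a difference of -0.75 (SE 1.32, limma adjusted p = 0.999). Adipocyte genes had a median of -0.65 (0 of 15 positive), with -0.65 (SE 0.61) for Scd1, an enzyme of fatty acid synthesis. With an estimated correlation the camera adjusted p was 0.919 for each of these lists. By limma 0 genes were called over all genes and 0 adjusted over the list alone, with 125 at an unadjusted p under 0.05 (42 higher, 83 lower) and a smallest adjusted p of 0.999. Signs of median, mean and test differed for 7 lists whose medians lay between -0.07 and 0.02, the regulatory T cell, macrophage, alternatively activated macrophage, VEGF, blood endothelial, immediate early and oxidative phosphorylation lists. Single arrays labelled shTGFb day 14 moved the medians, to 0.32 for interferon without array 3, to 1.81 for hair follicle without array 1, and to -0.59 for muscle and -0.21 for adipocytes without array 5.

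On the arrays labelled shVEGF day 4 keratinocyte genes had lower means than in control and inflammatory genes higher ones. Krt14 had a mean of 12.97 ± 1.87 (SD, n = 5) against 14.35 ± 0.12 (SD, n = 7), a difference of -1.37 (SE 1.35, limma adjusted p = 0.999), and all 18 keratinocyte genes had negative differences (median -2.09). Without shVEGF day 4 array 4, on which Krt1 was not detected, and 1 array labelled shTGFb day 4, the Krt14 difference was -0.62 and the mean difference of the list -1.09, beside -2.10 with all arrays. Inflammatory genes had a median of 0.68 (12 of 14 positive), interferon genes one of 0.57 (19 of 20) and oxidative phosphorylation genes one of 0.17 (17 of 17), with 0.06 (SE 0.10) for Atp5b, a subunit of ATP synthase. The camera adjusted p with an estimated correlation was 0.95 for each of these lists. By limma 0 genes were called over all genes, with 107 at an unadjusted p under 0.05 (61 higher, 46 lower) and a smallest adjusted p of 0.999, and 1 adjusted over the list alone, Clec4d, a lectin receptor of myeloid cells, at 1.54 (SE 0.51). Signs differed for the regulatory T cell list (median 0.04, mean -0.03, tested upward), the dendritic cell list (-0.10 and -0.07, upward), the hair follicle list (0.64 and 0.37, downward) and the immediate early list (0.01 and -0.14, downward). The oxidative phosphorylation median was 0.05 without shVEGF day 4 array 3 and 0.28 without array 1.

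Interferon response genes had positive differences for 20 of 20 members on the arrays labelled shVEGF day 14 against control, and the list was not called. Their median was 0.66, and the camera adjusted p of 0.0916 with an estimated correlation was the smallest of any list in the 13 comparisons. Irf7 had a difference of 0.77 (SE 0.42, limma adjusted p = 1.00), Stat2 one of 0.71 (SE 0.32) and Irf1 one of 0.39 (SE 0.36). Melanocyte genes had a median of -0.88 (1 of 13 positive), with Dct at 12.69 ± 2.55 (SD, n = 6) against 13.33 ± 2.28 (SD, n = 7), a difference of -0.65 (SE 1.15). That list had a camera adjusted p of 0.755 and a median of -0.09 without shVEGF day 14 array 2 and of -1.74 without control array 1. By limma 0 genes were called over all genes and 0 adjusted over the list alone, with 22 at an unadjusted p under 0.05 (13 higher, 9 lower) and a smallest adjusted p of 1.00. The Schwann cell list had a median of 0.03 with a mean of -0.01 and an upward test, and the oxidative phosphorylation list a median of -0.01 and a mean of -0.02 with an upward test. The interferon list passed with an estimated correlation without control array 6 (median 0.78, camera adjusted p = 0.0476) and without shVEGF day 14 array 1 (median 0.76, camera adjusted p = 0.0381). Under the other alternatives with an estimated correlation its camera adjusted p ranged from 0.0614 without background correction to 0.933 without shVEGF day 14 array 5 (median 0.45), with 0.433 for the replicate block. The lowest median was 0.41, without shVEGF day 14 array 3 (0.661).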

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

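The counts over other splits of the arrays and the fit with tissue lists as covariates were set before their results were seen, and all other tests in this part were chosen after the result was seen. Of 413 sets of values tested, each the values of 1 gene or list in 1 labelled group, 55 had an array far from the others, where chance flags about 1 in 20 sets, or 20.65. Each value below is followed by the range of the other arrays with the same label.

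Control array 6 had 12 such values. Its hair follicle list mean was 12.06 (others 5.32 to 7.53), its interferon list mean 10.49 (8.77 to 9.47), its adipocyte list mean 8.51 (10.23 to 10.92) and its alternatively activated macrophage list mean 7.69 (8.57 to 8.98). Among genes it had Dlx3 at 11.91 (7.48 to 9.34), Il1r2 at 7.44 (8.92 to 10.02), Ccl9 at 11.40 (12.38 to 12.80), Dcn at 13.07 (14.18 to 14.37), Myl1 at 13.29 (14.24 to 14.52), Scd1 at 12.25 (13.85 to 14.02), Klf6 at 11.21 (11.96 to 12.39) and Atp5b at 14.44 (14.35 to 14.38). Other arrays labelled control stood apart in Dct on array 1, 8.19 (13.70 to 14.53), Pdpn on array 1, 12.40 (11.46 to 11.73), Alas2 on array 2, 9.86 (5.81 to 7.36), and the oxidative phosphorylation list on array 5, 12.49 (11.62 to 11.91).

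Wild-type day 4 array 4 had 8, all of host tissue genes and all low. They were the means of the macrophage list, 4.68 (8.87 to 9.55), the dendritic cell list, 5.36 (8.58 to 9.23), the inflammatory list, 5.66 (7.93 to 8.35), and the blood endothelial list, 6.09 (8.13 to 8.52), with Lyz1 at 5.94 (14.01 to 14.53), Cd74 at 7.15 (13.75 to 14.21), Ccl9 at 4.48 (12.24 to 12.73) and Krt14 at 4.47 (13.80 to 14.54). Wild-type day 14 array 4 stood apart in the melanocyte list, 8.64 (11.13 to 11.90), and Dct, 12.81 (13.92 to 14.37).

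ShTGFb day 4 array 2 had 7, with high lymphocyte and low pigment genes. They were the melanocyte list, 5.89 (10.05 to 11.65), the T cell list, 9.91 (6.80 to 7.43), the B cell list, 9.72 (5.33 to 6.53), the blood endothelial list, 9.27 (7.99 to 8.46), Dct, 6.46 (13.77 to 14.24), Cd79b, 12.65 (5.46 to 6.74), and Myl1, 13.68 (14.19 to 14.47). In the same group, array 4 had Vegfb at 12.15 (10.55 to 11.07) and array 6 the inflammatory list at 8.73 (8.16 to 8.31). At day 14, shTGFb array 5 had the macrophage list at 8.49 (9.45 to 9.79), the alternatively activated macrophage list at 7.43 (8.73 to 9.23) and Retnla at 8.10 (12.59 to 13.93), and array 3 had Cd8b1 at 10.40 (10.84 to 11.01) and Pdpn at 10.75 (11.53 to 11.81).

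Among arrays labelled shVEGF day 4, array 5 had the muscle list at 7.59 (11.44 to 12.84), Myl1 at 10.65 (14.47 to 14.59) and Klf6 at 9.20 (11.82 to 12.17), array 2 had Dct at 8.07 (13.94 to 14.15) and array 4 had Dlx3 at 5.46 (9.02 to 9.49). At day 14, shVEGF array 3 had the protease list at 9.11 (9.37 to 9.46), the Schwann cell list at 7.11 (7.78 to 7.95), the oxidative phosphorylation list at 12.23 (11.80 to 11.91), Tgfbr2 at 11.61 (12.86 to 13.10) and Krt14 at 14.16 (14.42 to 14.58). Array 2 of that group had the B cell list at 4.74 (5.75 to 6.35), Tgfb1 at 8.39 (9.28 to 9.58), Dct at 7.77 (12.03 to 14.33) and Cd74 at 13.08 (14.18 to 14.42), and array 5 had Prf1 at 8.44 (9.38 to 9.87).

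For each of the 13 comparisons 100 splits of the arrays compared were counted. With 0 genes called by limma in each real split, 100 of 100 splits had to give as many, so the count of calls decides nothing about chance. At an unadjusted limma p under 0.05, the number of 100 splits with as many genes as the real one was 39 for wild-type day 4 against control, 8 for wild-type day 14, 6 for shTGFb day 4, 35 for shTGFb day 14, 73 for shVEGF day 4 and 86 for shVEGF day 14. It was 100 for wild-type day 14 against day 4, 15 and 28 for shTGFb against wild-type at days 4 and 14, 83 and 11 for shVEGF, and 83 and 87 for the differences between the days, so chance is not excluded for these counts either. The highest count of calls in another split was 0 for wild-type day 4, shTGFb day 4, shTGFb day 14, shVEGF day 4 and shVEGF day 14 against control and for shTGFb against wild-type at day 4. It was 3597 for wild-type day 14 against control, 2600 for wild-type day 14 against day 4, 4437 for shTGFb against wild-type at day 14, 3284 and 4626 for shVEGF against wild-type at days 4 and 14, and 3160 and 3662 for the differences between the days. Between 3 and 9 of the 100 splits in these 7 comparisons had calls, beside 0 in the real ones. Splits that called up to 4626 genes point to a structure of the samples other than the labelled groups.

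The labelled groups were little separated by their profiles, with a mean correlation of 0.874 within and 0.857 between labels (one-sided permutation p = 0.0465) and pigment genes high on most arrays labelled control. Growing hair follicles hold melanocytes and keratins together, so melanocytes of growing follicles in control tissue may raise Mlana, but 2 arrays labelled control had Mlana detected and Krt71 not detected, which argues against this as the whole cause. Tissue make-up of the pieces may hide group differences. With 5 tissue lists as covariates limma called 0 genes over the 13 comparisons, with 43 to 507 at an unadjusted p under 0.05. In the 11 comparisons simulated, this fit recovered 91 to 99.5% of changes of log2 2 and 42 to 71% at log2 1. Those changes were added independently of the covariates. In these 11 comparisons the 0 calls therefore argue only against hidden large changes that do not run with tissue make-up. Changes that run with the 5 lists would be taken up by the covariates, so the fit cannot decide on them. Labels attached to the wrong arrays cannot be told apart from groups that truly differ little, since 3 arrays had their most similar array under the same label, where chance gave 4.70. Biological differences between the lines and days stay open.

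The 3 arrays with host tissue genes near background were wild-type day 4 array 4 and wild-type day 14 arrays 2 and 5, with 17136, 17669 and 16519 detected probes, and wild-type day 14 array 2 had the lowest median raw signal of all arrays, 105. Low signal on these arrays as the whole cause is argued against, since the mean deposited log2 signal of the cell cycle list, before normalization, was 10.25 to 10.99 on them and above the median of the other arrays, 9.69, on 3 of 3. The highest of the other arrays had 10.78. On these 3 arrays 11 of 11 host lists were below the lowest other array, which restates how the arrays were chosen and tests nothing, and the B cell, hair follicle, mammary and Schwann cell lists, not among these 11, were not all below. RNA of tumour cells with little or no host tissue cannot be told apart from other causes, since the melanocyte list, not used to choose the arrays, was 11.26 to 11.60 on them, above the median of the others, 10.56, on 3 of 3 but above the highest, 12.36, on 0 of 3. A property of the wild-type tumours cannot be told apart from a difference in sampling, since 3 of the 9 wild-type arrays had the profile and 6 did not.

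Hair follicle keratins were high on some arrays and near background on others. The day after inoculation alone setting the keratins is argued against by Krt71, detected on 9 of 15 tumor arrays at day 4 and 9 of 16 at day 14 (Fisher exact p = 1). A fault of a single probe is argued against by Krt27, since Krt71 and Krt27 were both detected or both not detected on 36 of 38 arrays. The follicle's growth phase at sampling stays open, as the labels do not give it, and no biological explanation was tested.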

How the results depend on the processing

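Chosen after seeing the data were the removal of 3 arrays with collagen genes near background, the removal of 2 arrays far from the others and the fit with 5 tissue lists as covariates. The other alternatives were planned. Of 305 alternative counts of genes, 9 were above 0, and of 292 counts of lists with an estimated correlation, 2 were. No background correction, median scaling, the deposited normalized table, no detection filter, the mean of a gene's probes, the replicate block, a fit of only the groups compared and the 3 alternatives chosen later gave 0 genes called by limma in all 13 comparisons.

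With array weights limma called 778 genes for shTGFb day 4 against control and 855 against wild-type day 4. Vegfa passed with them at -0.79 (limma adjusted p = 0.014) and -0.77 (0.0317), while its adjusted p under the other alternatives lay between 0.845 and 1.00 and between 0.349 and 1.00. The cause was not tested.

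A preset correlation of 0.01 between the genes of a list gave 14 lists called by camera for wild-type day 4 against control, 14 for wild-type day 14, 6 for shTGFb day 4, 4 for shTGFb day 14, 4 for shVEGF day 4 and 8 for shVEGF day 14. It gave 13 for wild-type day 14 against day 4, 20 and 15 for shTGFb against wild-type at days 4 and 14, 20 and 18 for shVEGF, and 4 and 9 for the differences between the days. With the correlation estimated from the arrays, none of these calls held, and the smallest camera adjusted p was 0.0916. A preset correlation below the estimated one narrows the test by construction.

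Leaving out each array in turn gave 0 to 1436 genes by limma for wild-type day 14 against control, with 1436 without wild-type day 14 array 1 and 1271 without array 4. For shVEGF against wild-type at day 14 the range was 0 to 1627, with 1627 without wild-type day 14 array 4, 1210 without array 1 and 1 without array 3 (Irf7). For shTGFb against wild-type at day 14 it was 0 to 1, with Xkr7 called without wild-type day 14 array 1. For shTGFb day 4 against control it was 0 to 5, with Lef1, B3gnt5, Serpina1b, Serpina1d and Serpina1e called without shTGFb day 4 array 1. These called genes were chosen after their values were seen. The lists called for shVEGF day 14 against control ranged from 0 to 1, the interferon list without control array 6 and without shVEGF day 14 array 1, and the smallest adjusted p of that comparison ranged from 0.0381 to 0.933 over the alternatives with an estimated correlation. The other comparisons kept 0 genes and 0 lists without each array. Wild-type day 14 arrays 1, 3 and 4 were not host-poor, so the fits without them kept both host-poor arrays of that group. The cause was not tested.

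Of 9052 gene values under alternatives 714 had another sign, and 4 of the 715 whose gene passed the unadjusted threshold. The replicate numbers are those of the titles, and the descriptions give number 5 for every shTGFb and shVEGF sample, so the pairing check and the block rest on the titles. The mean correlation was 0.0778 over 102 pairs with the same number, 49 of them above 0.1, and -0.0101 over pairs with other numbers. Same-number pairs ranged from -0.807 to 0.750. The difference was not tested, so these values do not decide on pairing. A block for the number gave 0 genes by limma, with 17 to 2939 at an unadjusted p under 0.05. A block for the slide was not run, as the files give no slide. Between 36.5 and 50.6% of probes per array had a signal over background, which limits what can be said of genes such as Krt71, detected on 22 of 38 arrays.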

Other observations

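All relations and single arrays in this part were chosen after the data were seen. Over the 32 arrays with Mlana detected and host tissue genes present, the melanocyte list mean was compared with 11 other lists by permutation. The cell cycle list had a Spearman correlation of 0.888 with it (permutation p = 1e-05, the smallest possible) and a Pearson correlation of 0.760, and the hypoxia and glycolysis list 0.773 (permutation p = 1e-05, the smallest possible) and 0.761. Interferon response genes had 0.487 (permutation p = 0.00506, adjusted 0.00795) and oxidative phosphorylation genes 0.482 (0.00579, adjusted 0.00796). Host tissue lists had negative Spearman correlations, -0.759 for keratinocytes, -0.677 for the collagen list, -0.623 for macrophages, -0.552 for adipocytes and -0.418 for muscle, with adjusted permutation p from 5.5e-05 to 0.022. Their Pearson correlations were -0.453, -0.559, -0.455, -0.610 and -0.416 in the same order, with adjusted permutation p from 0.000623 to 0.0242. T cell genes had 0.132 (permutation p = 0.469) and blood endothelial genes -0.0620 (0.735). Without shVEGF day 4 array 2 and shVEGF day 14 array 1, the 2 of these 32 arrays whose melanocyte list mean lay farthest from the median, the Pearson correlations were 0.882 for the cell cycle, 0.695 for hypoxia, 0.484 for interferon and -0.686 for the collagen list. They were then -0.427 for keratinocytes, -0.605 for macrophages, -0.617 for adipocytes and -0.383 for muscle.

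Single arrays carried distinct tissue signals. ShTGFb day 4 array 2 had the B cell gene Cd79b at 12.65, the T cell gene Cd3g at 11.22 and the epithelial keratin Krt8 at 12.39, with the pigment genes Mlana at 4.57 and Pmel at 4.38. ShVEGF day 4 array 4 had the alternatively activated macrophage genes Arg1 at 13.39 and Chil3 at 12.95, and Krt1, a keratin of the upper epidermis, was not detected on it. Wild-type day 14 array 4 had the hair follicle list at 12.78 and S100a8 at 11.19. ShVEGF day 14 array 3 had the highest interferon list mean of all arrays, 11.33, with Cxcl9, a chemokine induced by interferon gamma, at 12.92 and the guanosine triphosphatase Igtp at 13.36. Control array 6 had Mlana at 14.49, Krt71 at 14.35, Cxcl9 at 12.03 and Igtp at 12.78. Mlana was near background on control array 1 (4.62), shVEGF day 4 array 2 (5.35) and shVEGF day 14 array 2 (4.60).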
